A study of Mus musculus with 9 samples.

How the data were processed

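Total RNA of 9 mouse cell cultures was labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The groups were EpiSCs with vehicle, EpiSCs with IWP2 and ESCs, each with 3 arrays that the labels call biological replicates. The concentration and duration of IWP2 are not given in the sources used here. The labels' treatment protocol also mentions Wnt3a given after IWP2, and such samples are not analysed here. Scan dates were not used here, so batches could not be examined.

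The authors deposited a table of log2 values for 45101 probe sets. The submitters' processing notes name RMA and limma, without versions. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each set, and the arrays' medians (5.22 to 5.26) were accordingly close. The quartiles differed slightly between cell types. Lower quartiles were 3.664 to 3.692 on EpiSC arrays and 3.788 to 3.801 on ESC arrays, and upper quartiles 7.415 to 7.45 and 7.294 to 7.317. Quantile normalization gives the arrays nearly the same distribution, so a change of total RNA per cell would not be seen, and summarised values carry no detection calls. The lower quartile of all values was 3.72. Signals at this floor compress differences, and a log2 difference against a gene at the floor is then better read as a lower limit of its size.

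Probe sets were named through the platform annotation. Of them 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. Of the single symbols 34754 were found by gene identifier in the RefSeq table of the mouse assembly GRCm38.p6, and 0 of them had changed. Only probe sets with 1 symbol were tested. For each gene the probe set with the highest mean over the 9 arrays was used, which gave 18193 genes. A called gene named in the text had no probe set called in the opposite direction, except Stard4 for ESC minus vehicle and Impact for ESC minus IWP2. The RefSeq table was also used for the chromosome of each gene.

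Means per group were fitted to all 9 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 6 residual degrees of freedom and 9.58 after moderation). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. Genes with an adjusted p under 0.05 are called, and those with an absolute log2 difference of at least 1 are counted as 2-fold. The median standard error of a difference between 2 groups was 0.082. Adjusted p-values of genes in the text are from limma. A total of 28 gene lists holding 430 genes, of which 399 were measured, were fixed before the data were examined. So were the tests and the alternatives, except those that the text says were added or chosen later. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists tested in a comparison. Camera was repeated with the correlation estimated for each list, since the preset value gives smaller p where the members of a list move together.

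Genes named in the text follow a rule fixed before the data were examined. For IWP2 minus vehicle and ESC minus vehicle these are the 10 largest rises and 10 largest falls, and for ESC minus IWP2 the 5 largest of each. They had to be called, to have a mean in the higher group at or above 5.24 (the median of all probe sets) and to have no overlap between the 3 arrays of one group and the 3 of the other, which chance gives 10% of genes. Probe sets ending in _x_at, Riken clones and Gm models were passed over. A further 9 genes were fixed by name, of which 8 were measured and 1 is not reported here. Of each list described, up to 2 called members with the smallest p were named in each direction, or the 2 with the smallest p where none was called. Genes outside the rule are said to be so.

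The test was checked on simulated data for IWP2 minus vehicle, with 18193 genes and the spread of the real arrays. Of 50 changed genes per size, 26% were called at a log2 change of 0.3, 74% at 0.5 and 100% at 1 and at 2, and 4.46% of all calls were of unchanged genes. In a simulation of ESC minus vehicle with the members of 1 list shifted by 0.5 log2, camera ranked that list first and called 1 list of 27.

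Alternatives tried were all named probe sets or the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, a filter on low signal, an offset of 32 on the linear scale, repeated quantile normalization, cyclic loess, median centring, other variance models (trend and robust, array weights), fits of only the arrays compared, a replicate block, an adjusted p under 0.01, limma's treat with a minimum log2 difference of 1, other set tests (fry, camera on ranks) and leaving out each array. A test without the sex chromosomes and the overlap of the IWP2 and ESC minus vehicle changes were added after the data had been seen.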

Results

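RNA levels were measured on 9 Affymetrix Mouse Genome 430 2.0 arrays, with 3 biological replicates in each of 3 groups. Epiblast stem cells (EpiSCs) are pluripotent cells of the kind found in the epiblast after implantation and are called primed. Embryonic stem cells (ESCs) stand for the earlier, naive state. The first group held EpiSCs given vehicle, which the study calls conventional, and the second held EpiSCs given IWP2, an inhibitor of the acyltransferase Porcupine that stops cells from secreting Wnt proteins. EpiSCs grew with Activin A at 20 ng/ml and bFGF at 12 ng/ml, and ESCs, the third group, with LIF at 1000 U/ml and Wnt3a at 250 ng/ml, so that cell type and medium changed together. All cells are labelled with the mouse strain C57BL/6. The arrays give no read depth, and their number, 3 per group, limits the precision.

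The 3 groups were well apart. Across all probe sets, replicates of 1 group correlated at 0.997 to 0.998 and vehicle with IWP2 arrays at 0.982 to 0.985. EpiSC arrays correlated with ESC arrays at 0.927 to 0.931. The first principal component held 82.4% of the variance and separated ESCs from both EpiSC groups. The second held 13.8%, placed vehicle arrays at -31.3 to -34.4 and IWP2 arrays at 31.1 to 33.4, and left the ESC arrays between 0.201 and 0.542. RNA quality signs were close but not equal. The 3' minus 5' difference of the actin control probe sets was 0.53 to 0.59 log2 on vehicle arrays, 0.64 to 0.69 on IWP2 arrays and 0.64 to 0.66 on ESC arrays, and that of the Gapdh controls lay between -0.06 and 0.00 on all 9.

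**Figure D1:**
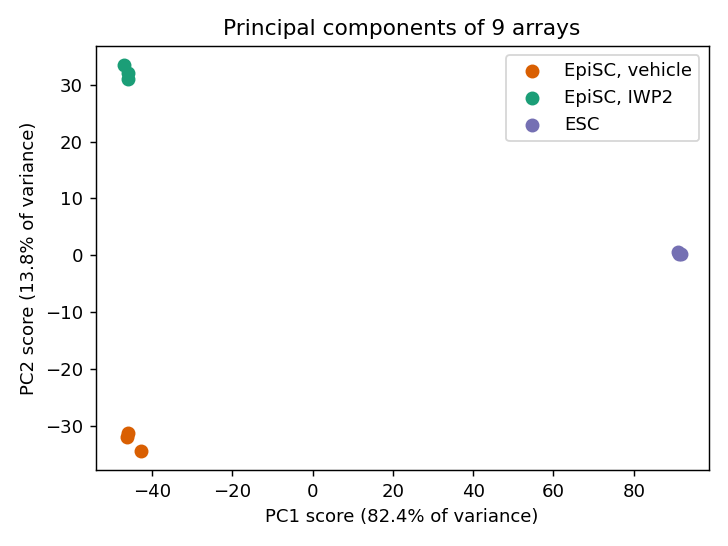
Scores of the 9 arrays on the first 2 principal components of 18193 genes (x axis 82.4%, y axis 13.8% of the variance, no unit), each point 1 array coloured by group. ESC arrays sit near 91 on the first axis and both EpiSC groups between -42.7 and -47.1, while the second axis separates vehicle from IWP2.

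The first comparison asked what blocking the release of endogenous Wnt proteins does to EpiSCs. The largest fall with IWP2 was that of Spink1, a secreted trypsin inhibitor, from 10.30 ± 0.051 to 2.92 ± 0.236 (mean log2 signal ± SD, n = 3), a difference of -7.37 ± 0.118 (SE). Lhx1, a homeobox gene of the node and anterior mesendoderm, fell by 6.98 ± 0.104, and the apelin receptor gene Aplnr fell by 7.35 ± 0.157. Shh, the hedgehog ligand of notochord and endoderm, fell by 6.65 ± 0.098, and Foxa2, a forkhead factor of endoderm and midline, fell by 6.07 ± 0.107. The other 5 of the 10 largest falls were Bmp2 (-6.27), Pga5 (-5.84), Slit2 (-5.72), Hesx1 (-5.45) and Cer1 (-5.42), with limma adjusted p of 7.6e-09 or smaller for all 10. After IWP2, 9 of these 10 genes had mean levels of 2.92 to 4.27, against a lower quartile of 3.72 for all values, so their differences are limited by the floor of the array. Pga5 ended at 4.58.

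Rises with IWP2 were smaller. Klhl14 rose from 3.58 ± 0.260 to 6.52 ± 0.366 (SD, n = 3), a difference of 2.94 ± 0.203 (SE) with limma adjusted p = 3.93e-06. Lrrn1, a leucine-rich repeat membrane protein of the nervous system, rose by 2.65 ± 0.121, the matrix protein gene Matn3 by 2.56 ± 0.166 and Rasd2 by 2.52 ± 0.084. Without probe sets ending in _x_at or _s_at the Rasd2 difference was 0.25 and was not called. Cbln4 (2.38), Scg5 (2.28), Dcaf12l1 (2.26), Sytl2 (2.21), Kctd12b (2.20) and Prox1 (2.16), a homeobox gene, completed the 10 largest rises. Of 18193 genes tested, limma called 6094 at an adjusted p under 0.05, 3029 of them higher and 3065 lower with IWP2. Most of these changes were small. Only 164 genes rose and 512 fell by at least 2-fold, and 25 fell and 0 rose by at least 16-fold. With an offset of 32 on the linear scale the 2-fold counts were 84 and 265, and among genes above the median signal 337 fell. At an adjusted p under 0.01, 3886 genes were called. A test against a minimum change of 2-fold called 51 rises and 294 falls.

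**Figure D2:**
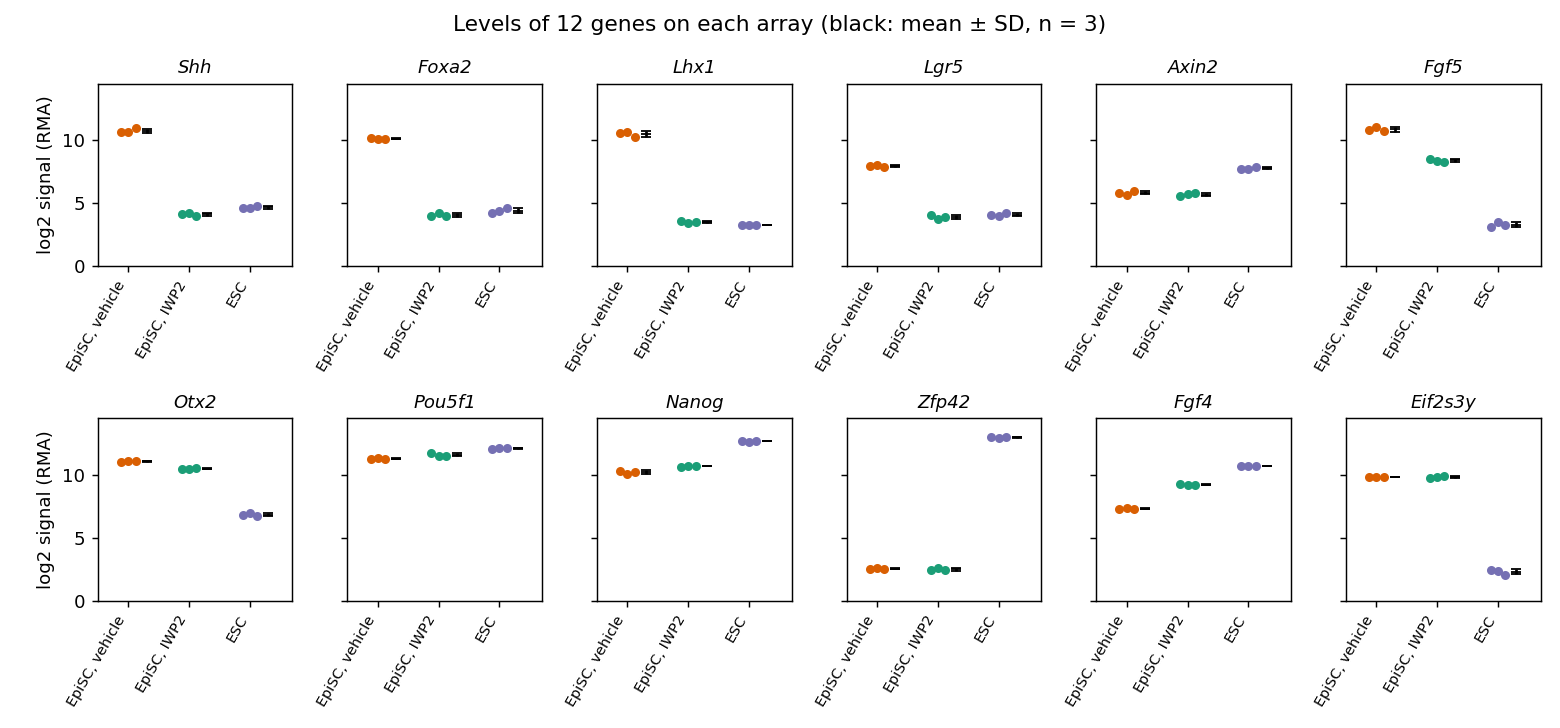
Log2 RMA signal (y axis) of 12 genes on each of the 9 arrays, by group (x axis); points are arrays and black marks the mean ± SD of 3. Shh, Foxa2, Lhx1 and Lgr5 were high only with vehicle, Axin2 was at 5.83 and 5.66 in the EpiSC groups, and Zfp42 was high only in ESCs.

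Definitive endoderm genes were the list that moved most with IWP2. Of 12 measured members, 11 fell, each by at least 2-fold, and 0 rose, with a median of -3.91 (camera adjusted p = 2.57e-17, and adjusted p = 0.0171 with an estimated correlation). The homeobox gene Hhex fell by 4.05 ± 0.063. Among the extraembryonic endoderm genes, which share several factors with definitive endoderm, 8 of 16 fell and 0 rose (adjusted p = 0.000285, and 0.033 with an estimated correlation), including Gata6 (-3.99) and Sox17 (-3.35). Primitive streak and mesoderm genes split. Of 21 measured, 9 fell, 8 of them by at least 2-fold, 1 rose and 11 were not called. Lhx1 and the organizer gene Gsc (-3.83 ± 0.113) fell, and Tbx6 rose by 0.52 ± 0.137 at a level of 3.87, close to the array floor and not called without vehicle replicate 1. That list passed with the preset correlation (camera adjusted p = 0.000458) and lost its call with an estimated one (adjusted p = 0.152). Of 12 trophoblast genes, 4 fell and 0 rose (adjusted p = 0.0193, and 0.115 with an estimated correlation). Eomes (-3.62), which also marks the primitive streak, and the keratin gene Krt7 (-3.19) led these falls.

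Wnt feedback and target genes fell in part. Of 19 measured, 9 fell, 6 of them by at least 2-fold, 0 rose and 10 were not called (camera adjusted p = 8.73e-06, and 0.0171 with an estimated correlation). Lgr5, a receptor for R-spondins, fell from 7.93 ± 0.054 to 3.88 ± 0.145 (SD, n = 3), and Tnfrsf19 fell by 3.80 ± 0.109. Axin2, often used as a Wnt readout, was low in both EpiSC groups, at 5.83 ± 0.153 and 5.66 ± 0.111 (SD, n = 3), and was not called (difference -0.17 ± 0.089 SE, limma adjusted p = 0.191). Among 21 genes for Wnt ligands and Wnt secretion, 8 fell and 1 rose, without a call for the list (camera adjusted p = 0.0528). Wnt5a (-1.58) and Wnt8a (-1.41) fell and Wnt4 rose by 0.64.

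FGF/ERK target genes also fell together, with bFGF in the medium of both EpiSC groups. Of 15 measured, 12 fell, 1 rose and 2 were not called (camera adjusted p = 9.65e-08, and 0.0171 with an estimated correlation). Dusp4, a MAP kinase phosphatase gene, fell by 3.10 ± 0.112 and the immediate early gene Egr1 by 2.39 ± 0.103, while the ETS factor gene Etv5 rose by 0.20 ± 0.068 (SE), a call that leaving out single arrays could end. Of 11 Nodal/Activin target genes, 7 fell, 4 of them by at least 2-fold, and 2 rose, with a median of -0.26 (camera adjusted p = 0.000458, and 0.197 with an estimated correlation). The list shares Cer1 and Gsc with the definitive endoderm list and Eomes with the primitive streak list. It is therefore not independent of the falls in those lists. Cer1 and Gsc had the smallest p among the falls, and Smad7 (0.25) and Skil (0.23) were the rises. The Skil value rests on 1 of 2 probe sets: the mean of both was -0.13 and was not called.

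Pluripotency genes moved in both directions. Pou5f1, which encodes Oct4, rose by 0.31 ± 0.077 (limma adjusted p = 0.011) and Nanog by 0.47 ± 0.070 (adjusted p = 0.00069), and Sox2 fell by 0.20 ± 0.065 (adjusted p = 0.042), a call that leaving out single arrays could end. Of 13 general pluripotency genes, 3 rose, 5 fell and 5 were not called (camera adjusted p = 0.314), with Sall4 at -0.92 and Utf1 at 0.54. Of 19 naive pluripotency genes, 4 rose, 5 fell and 10 were not called (camera adjusted p = 0.873). Fgf4, a growth factor gene of the inner cell mass, rose from 7.33 ± 0.050 to 9.22 ± 0.052 (SD, n = 3), whereas Klf5 fell by 1.15, Tfcp2l1 fell by 0.70 (-0.16 and not called as the mean of its probe sets), and Zfp42, the gene for Rex1, stayed near the floor (difference -0.07, adjusted p = 0.452). Primed epiblast genes went both ways, with 7 of 17 higher, 7 lower and 3 not called (camera adjusted p = 0.211). Fgf5 fell from 10.86 ± 0.179 to 8.38 ± 0.135 (SD, n = 3), Lefty2 (-2.55), Cd24a (-1.96) and Otx2 (-0.59) fell, and Sox3 (1.37) and Zic5 (0.85) rose. Cdh1, the gene for E-cadherin, fell by 0.45 ± 0.063.

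Cholesterol biosynthesis genes rose with IWP2. Of 19 measured, 15 rose, 1 fell and 3 were not called, with a median of 0.57 (camera adjusted p = 9.76e-08). This call was lost with an estimated correlation (adjusted p = 0.188). Mvd, a mevalonate pathway enzyme, rose by 1.27 ± 0.064 and Insig1, a sterol-responsive regulator, by 1.20 ± 0.079, and Ebp fell by 0.43. Proliferation and mitosis genes rose slightly, 13 of 19 with a median of 0.22 and 1 lower (adjusted p = 0.000426, and 0.0708 with an estimated correlation). Mki67 rose by 0.56 and Bub1 by 0.52, and the cyclin gene Ccne2 fell by 0.96.

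Markers of other cell types that a culture could hold moved in both directions. Neurectoderm genes gave 3 rises, 4 falls and 8 genes not called out of 15, and the list did not pass (camera adjusted p = 0.964). Its median was 0.14 and its mean -0.34, because Hesx1 (-5.45) and Six3 (-1.70), genes of the anterior neural plate, fell while Ncam1 (0.89) and Tubb3 (0.73) rose. Neural crest genes gave 3 rises, with Ets1 at 1.64 and Snai2 at 1.11, and 3 falls, with Sox9 at -1.88, out of 12 (adjusted p = 0.856). Fibroblast and feeder cell genes gave 2 rises and 6 falls out of 14 (adjusted p = 0.0719), with Col3a1 at -2.30 and Dcn at 0.78. Of 16 genes of the epithelial-mesenchymal transition, 4 rose and 7 fell (adjusted p = 0.143), among them Cdh2 (-1.42), the gene for N-cadherin, and Fn1 (-1.38). Adjusted over the list alone, the called members were 11 of definitive endoderm, 9 of Wnt targets, 10 of primitive streak and mesoderm, 14 of FGF/ERK targets and 17 of cholesterol biosynthesis. On the same basis they were 17 of proliferation, 10 of naive, 16 of primed epiblast, 10 of Nodal/Activin, 9 of neurectoderm, 7 of neural crest, 9 of fibroblast and 12 of epithelial-mesenchymal transition genes, and in the remaining lists described for IWP2 up to here they equalled the counts over all genes.

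**Figure D3:**
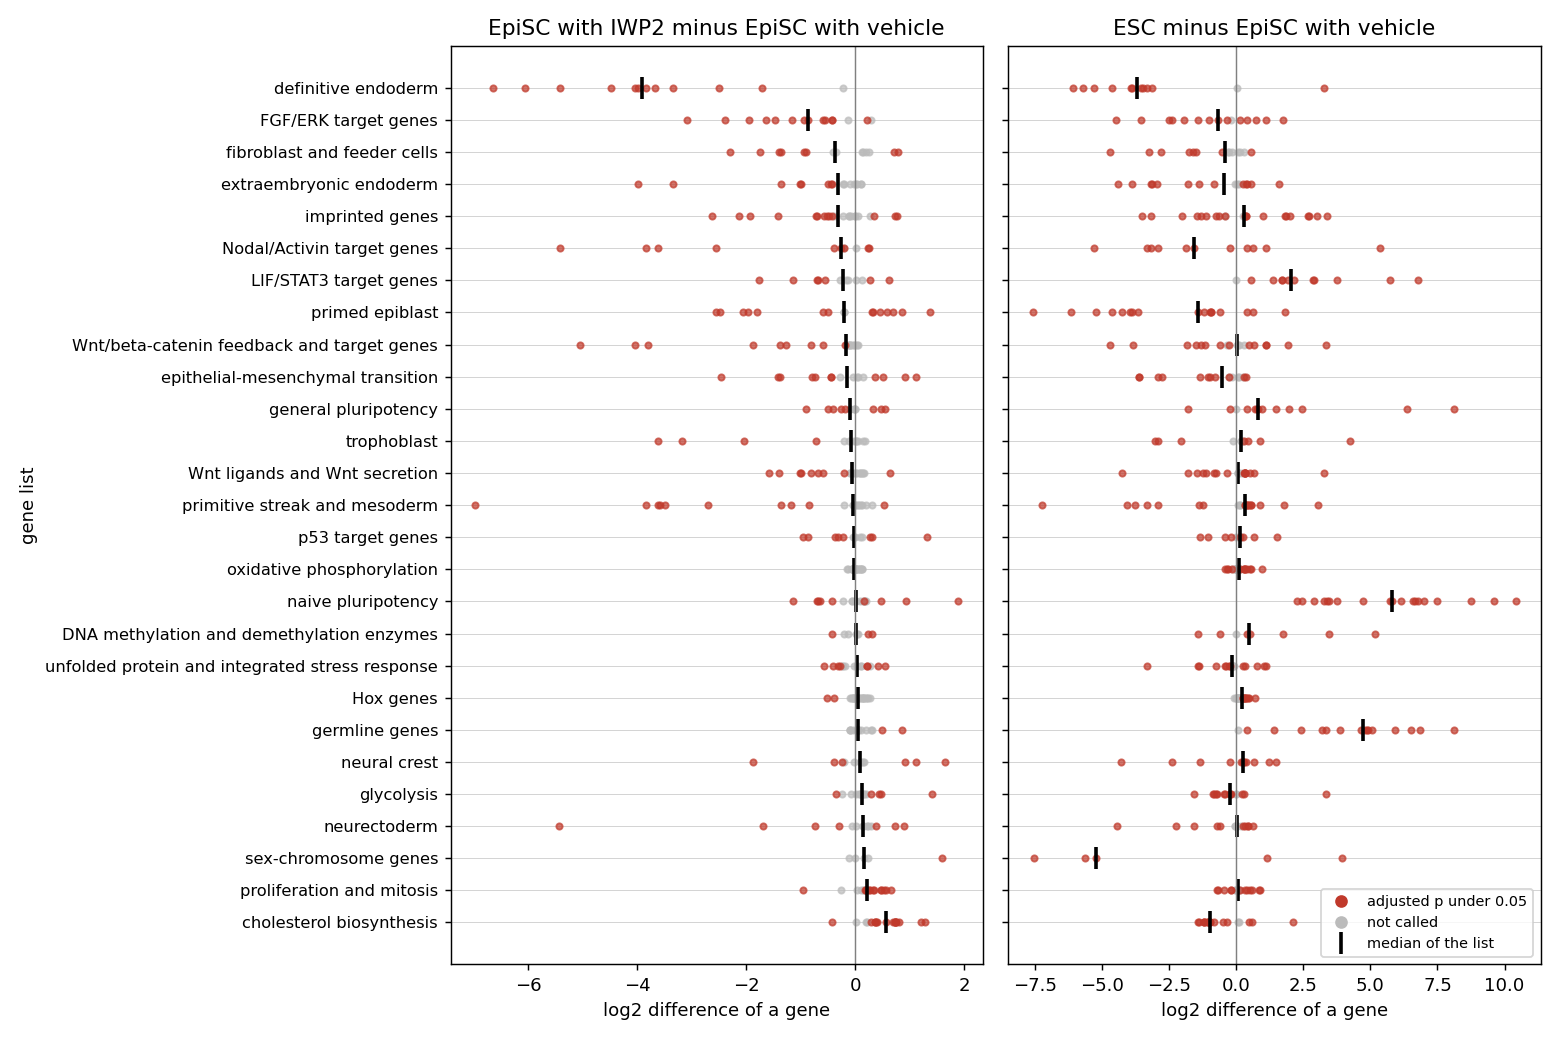
Log2 differences (x axis) of the measured members of the 27 gene lists tested (y axis), for IWP2 minus vehicle and ESC minus vehicle; each point is a gene, red where its adjusted p was under 0.05, and black bars are list medians. Definitive endoderm genes had a median of -3.91 with IWP2, and naive pluripotency genes a median of 5.80 in ESCs.

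The comparison of ESCs with conventional EpiSCs set the naive against the primed state, but not the state alone. These groups also differed in medium and, as described below, in sex-chromosome genes, so the differences cannot be assigned to the state. The p-values rest on the spread between replicate cultures, and a spread between cell lines was not examined. Zfp42 was at 12.98 ± 0.041 in ESCs and at 2.54 ± 0.013 in vehicle EpiSCs (SD, n = 3), a difference of 10.44 ± 0.062 (SE). Next came Dppa5a (9.62), Rps4l (9.28), the germline gene Morc1 (9.11), the orphan nuclear receptor gene Nr0b1 (8.74), Mageb16 (8.36), Dppa2 (8.12), Rhox5 (8.10), Efhc2 (7.71) and Phf11d (7.55), with limma adjusted p of 2.03e-11 or smaller. In the other direction the zinc transporter gene Slc39a8 came first (-8.93 ± 0.087, SE), followed by Klhl4 (-8.63), Pkdcc (-8.03), Amot (-7.86), Aplnr (-7.80) and the primed growth factor gene Fgf5 (-7.58). Eif2s3y (-7.54), which is Y-linked, Lhx1 (-7.24) and the simple epithelial keratin genes Krt8 (-6.73) and Krt18 (-6.57) completed the 10. In all, limma called 12123 genes, 7045 higher and 5078 lower in ESCs, and 1249 and 1752 of them by at least 2-fold. The median difference over all genes was 0.12, against which small differences must be read. Among genes with a mean above the median of all probe sets, 4193 were higher and 4550 lower, with 815 higher by at least 2-fold. With an offset of 32, 812 were higher by at least 2-fold.

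All 19 measured naive pluripotency genes were at least 2-fold higher in ESCs than in vehicle EpiSCs, with a median of 5.80 (camera adjusted p = 5.39e-14, and 0.00682 with an estimated correlation). Prdm14, a factor of naive and germ cells, was higher by 6.68 ± 0.052. Of 16 germline genes, 15 were higher and 1 was not called (adjusted p = 3.65e-09, and 0.00682 with an estimated correlation), with Hormad1 at 6.85. LIF was present in the ESC medium alone, and 11 of 12 LIF/STAT3 target genes were higher in ESCs and 0 lower (adjusted p = 4.8e-06, and 0.152 with an estimated correlation), with Klf4 at 6.78 and Tfcp2l1 at 5.73. The LIF/STAT3 list shares several members, both of these among them, with the naive pluripotency list. It is therefore not independent of that list. Of 13 general pluripotency genes, 10 were higher and 2 lower (adjusted p = 0.00603, and 0.364 with an estimated correlation). Nanog was higher by 2.46, Sox2 by 1.98 and Pou5f1 by 0.82, and Lin28a was lower (-1.79 ± 0.086).

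Primed epiblast genes were lower in ESCs for 14 of 17 members and higher for 3 (camera adjusted p = 1.26e-06, and 0.0293 with an estimated correlation). Sox4 (-6.17), Cd24a (-4.63) and Otx2 (-4.25) were among the lower genes, and Grhl2 (1.83) and Lefty2 (0.63) were higher. Definitive endoderm genes were lower for 10 of 12, with 1 higher (adjusted p = 1.26e-06, and 0.0622 with an estimated correlation). Shh differed by -6.10, and Trh, the gene for thyrotropin-releasing hormone, was the member that was higher (3.28). Wnt target genes went both ways in ESCs, whose medium contained Wnt3a. Of 19, 6 were higher and 8 lower (adjusted p = 0.396), with Axin2 (1.93) and the Wnt deacylase gene Notum (3.35) higher and Lgr5 (-3.85) and Dkk1 (-4.69) lower. The list of Wnt ligands and secretion genes had 8 higher and 8 lower members of 21 (adjusted p = 0.659), with Porcn, which encodes the target of IWP2, at 3.29 and the Wnt carrier gene Wls at -4.26. For primitive streak and mesoderm genes, 11 were higher and 7 lower of 21 (adjusted p = 0.87). The median of this list was 0.32 and its mean -0.68, with Bmp4 at 3.05 and Fgf8 at -4.07.

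Several further lists were lower in ESCs than in vehicle EpiSCs with the preset correlation and were not called with an estimated one. Cholesterol biosynthesis genes were lower for 14 of 19 and higher for 3 (adjusted p = 0.000669, and 0.369 with an estimated correlation), with Tm7sf2 at -1.21 and Ebp at 2.13. Genes of the epithelial-mesenchymal transition were lower for 9 of 16 and higher for 2 (adjusted p = 0.00322, and 0.323 with an estimated correlation), including Cdh2 (-3.62). FGF/ERK target genes were lower for 9 of 15 and higher for 5 (adjusted p = 0.0224, and 0.192 with an estimated correlation), with Egr1 at -4.48 and Etv5 at 1.74. Extraembryonic endoderm genes had 8 lower and 5 higher members of 16 (adjusted p = 0.0261, and 0.152 with an estimated correlation), and fibroblast and feeder cell genes 7 lower and 1 higher of 14 (adjusted p = 0.0224, and 0.369 with an estimated correlation). The smooth muscle actin gene Acta2, a member of the last list, differed by -4.69, and by -0.07, not called, without probe sets ending in _x_at or _s_at. Of 15 glycolysis genes, 10 were lower and 3 higher (adjusted p = 0.0451, and 0.61 with an estimated correlation), with Eno3 at -1.56 and Pfkp at 3.36. Adjusted over the list alone, the calls for ESC minus vehicle were 19 naive, 15 germline, 17 primed epiblast, 11 definitive endoderm, 15 Wnt target, 17 cholesterol and 13 epithelial-mesenchymal transition genes.

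Against IWP2-treated EpiSCs, ESCs differed in a similar number of genes. Limma called 11298 genes, 6400 higher and 4898 lower in ESCs, with 1432 and 1711 by at least 2-fold. Among genes with a mean above the median of all probe sets, 4322 were higher and 4511 lower. The 5 largest rises were those of Zfp42 (10.51), Dppa5a (9.84), Rps4l (9.25), Morc1 (9.22) and Nr0b1 (8.81), and the 5 largest falls those of Slc39a8 (-9.80), Klhl4 (-9.54), Eif2s3y (-7.52), Jph1 (-6.56) and Sox4 (-6.49). All 19 naive genes were higher (camera adjusted p = 7e-14, and 0.00711 with an estimated correlation), as were 15 of 16 germline genes (adjusted p = 4.97e-09, and 0.00711), and 14 of 17 primed epiblast genes were lower, with 3 higher (adjusted p = 3.51e-06, and 0.0365). Fgf5 was lower in ESCs than in IWP2-treated EpiSCs (-5.11 ± 0.120). Of 12 definitive endoderm genes, 5 were higher in ESCs, 1 was lower and 6 were not called (adjusted p = 0.455). Apela was the lower member (-0.96) and Trh (4.99) the highest. Of 19 cholesterol biosynthesis genes, 16 were lower in ESCs and 1 higher (adjusted p = 8.8e-08, and 0.327 with an estimated correlation), with Msmo1 at -1.72. LIF/STAT3 targets (11 of 12 higher, adjusted p = 3.51e-06), general pluripotency genes (11 of 13 higher, 1 lower, adjusted p = 0.000888), genes of the epithelial-mesenchymal transition (10 of 16 lower, 3 higher, adjusted p = 0.00786) and glycolysis genes (10 of 15 lower, 1 higher, adjusted p = 0.00786) also passed. With an estimated correlation these 4 lists had adjusted p of 0.205, 0.327, 0.412 and 0.456. Of 19 Wnt targets, 9 were higher and 4 lower in ESCs (adjusted p = 0.286), with Tnfrsf19 at 4.29. Adjusted over the list alone, 19 naive, 17 primed epiblast, 6 definitive endoderm, 18 cholesterol and 14 Wnt target genes were called.

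The difference with IWP2 was set beside the contrast of ESCs against the mean of both EpiSC groups, whose chance values are uncorrelated with those of the IWP2 contrast if both EpiSC groups vary alike. A change with IWP2 still moves the EpiSC mean, so the 2 are not free of each other where IWP2 has an effect. That contrast called 12520 genes, 7272 higher and 5248 lower in ESCs, with 1300 and 1693 by at least 2-fold. Above the median signal 4401 were higher, 865 of them 2-fold, and 4675 were lower. With the offset 843 were 2-fold higher. Across 18193 genes, which are not independent replicates, the 2 differences had a Pearson r of -0.016 and a Spearman rho of -0.083. In 100 simulated data sets with no effect, r lay between -0.019 and 0.020. That range holds noise alone. It does not show what unrelated real changes would give, and rho was not simulated. Among genes with a mean above the median of all probe sets r was -0.066. Of 512 genes at least 2-fold lower with IWP2, 190 were at least 2-fold lower and 86 higher in ESCs than in the EpiSC mean, and of 164 genes at least 2-fold higher with IWP2, 98 were lower and 17 higher, counts that the IWP2 arrays in that mean partly set. Against vehicle alone, 338 of the 512 were at least 2-fold lower in ESCs and 50 higher, where independent lists would share 49.31 and 35.15, and of the 164, 59 were lower and 25 higher, against 15.79 and 11.26. In 100 simulated data sets with no effect each of these 4 counts was 0. Without an effect hardly any gene can be called at 2-fold, so this says nothing about the excess. Part of the excess may come from the shared vehicle arrays. The counts for independent lists also run over all 18193 genes, including genes near the floor that can hardly fall. Lrrn1 was at 5.50 with vehicle, 8.15 with IWP2 and 3.61 in ESCs, and Klhl14 at 3.58, 6.52 and 3.33. Fgf4 was at 7.33, 9.22 and 10.70 and Dcaf12l1 at 4.80, 7.06 and 9.12 in the same order.

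**Figure D4:**
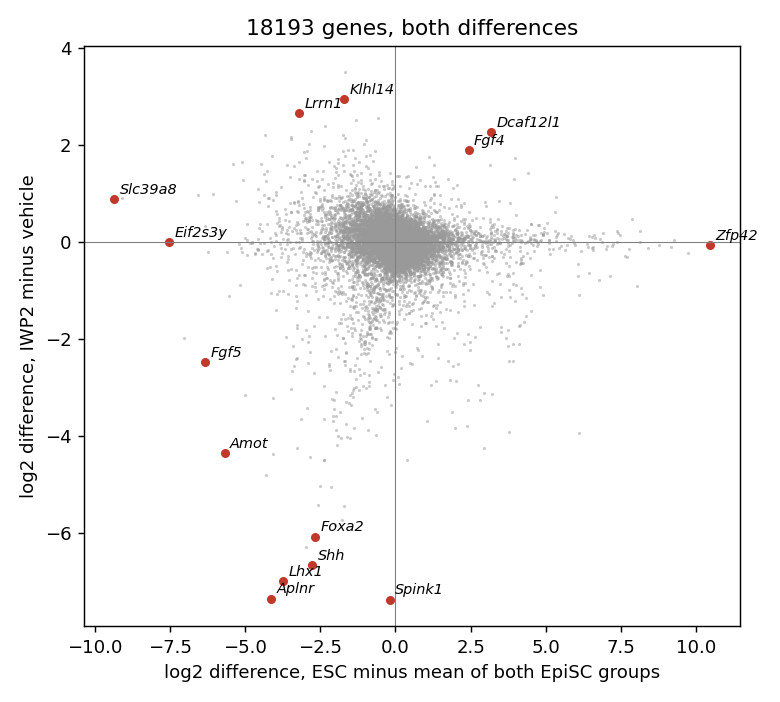
Log2 difference of IWP2 minus vehicle (y axis) against that of ESC minus the mean of both EpiSC groups (x axis) for 18193 genes, 1 point per gene, with named genes in red. Pearson r was -0.016 and Spearman rho -0.083, with Shh, Lhx1 and Foxa2 low on both axes and Zfp42 high on the ESC axis.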

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

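The tests of array scaling for the Y-linked and endoderm genes, of the neurectoderm list and of the Wnt target list were chosen after the values they measure had been seen. Probe sets left out of the gene tests, because the annotation gives them several symbols or none, also changed. Of 10092 such probe sets, limma called 160 at least 2-fold changed with IWP2 (51 higher and 109 lower), 908 for ESC minus vehicle and 958 for ESC minus IWP2. These are signals outside the genes reported on, and no gene names are attached to them here.

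The 6 arrays of each comparison were also regrouped 3 against 3 in the fit to all 9 arrays. The real counts of called genes were 6094 for IWP2 minus vehicle, 12123 for ESC minus vehicle and 11298 for ESC minus IWP2, and the highest of the other 9 splits called 0 in each. Only 1 of 10 splits was as large each time, and 10 splits are too few for a share under 0.05. For called lists the real counts were 11, 12 and 8 and the highest others 7, 9 and 8, so that for ESC minus IWP2 a total of 2 of the 10 splits called as many lists. Among 84 splits into 3 and 6 arrays, 1 gave as many genes as ESC against both EpiSC groups (10393 in a 2-group fit). The highest other gave 1783. Every other split puts ESC and EpiSC arrays together on at least 1 side, which widens the spread and lowers the count. The splits 3 against 3 likewise mix 2 distinct groups. Neither set of splits therefore decides whether chance in the grouping could give the real counts.

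Sex-chromosome genes separated ESCs from both EpiSC groups. The 3 Y-linked genes above the median signal in EpiSCs, Eif2s3y, Kdm5d and Uty (of these Uty alone is outside the naming rule), had EpiSC means of 9.83, 8.30 and 7.56 and ESC means of 2.29, 2.55 and 2.41, and Xist went from 5.14 with vehicle and 6.73 with IWP2 to 9.07 in ESCs on 1 of its 3 probe sets, with the other 2 at 3.75 or lower in every group. Array scaling is argued against, since at most 0.0257% of autosomal genes at a like EpiSC level fell as far as a Y-linked gene. The median ESC minus EpiSC difference of 360 X-linked genes above the median signal was 0.481, above every single autosome (-0.16 to 0.22). Of 10000 random gene sets, 0% reached it. This goes with 2 active X chromosomes in the ESCs against 1 in the EpiSCs as a hypothesis. The Xist signal is not taken as support for that hypothesis. Its strongest probe set also rose with IWP2, while Eif2s3y stayed at 9.83 with vehicle and 9.82 with IWP2. The other 2 Xist probe sets did not rise with IWP2 (2.571 to 2.48 and 3.094 to 3.084). They were higher in ESCs (3.301 and 3.751), but near the array floor. Whether the lines came from embryos of different sex, or the ESCs lost the Y chromosome, stays open, because no label gives the sex and the groups differ in cell type too.

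Endoderm genes were lower with IWP2 by a median of 3.91 (log2 difference -3.91). Array scaling is argued against by the spiked control probe sets, of which none differed by more than 0.416 between the 2 EpiSC groups. A loss of differentiated cells of every kind stays open, because the neurectoderm list (median 0.139) had members called in both directions. The fall of the Wnt target list (camera adjusted p 8.73e-06, and 0.0171 with an estimated correlation) goes with blocked Wnt secretion as a candidate explanation. However, the median of this list was only -0.165, and 10 of its 19 members, Axin2 among them, were not called. A loss of cells that express some of its members could lower the list too, so its fall does not decide. A subset of endoderm-like cells in the vehicle cultures and a lower level in every cell cannot be told apart on arrays of whole cultures. All 12 measured endoderm genes ended within 1 log2 of their ESC level or under it, which either would give. The ESC level is not a floor for all of them: Trh was at 9.31 in ESCs and 4.33 with IWP2, and Apela was still at 8.49 with IWP2. The fall of 1 of the 12 with IWP2 was not called.

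Cholesterol biosynthesis genes were higher with IWP2 by a median of 0.565. Without probe sets ending in _x_at or _s_at the median was 0.565, against a median standard error of 0.069. This argues against such cross-hybridising probe sets. Under the rescalings the median of the list was at least 0.579. The values were already quantile-normalized, and the rescalings moved the median of all genes only from 0.0332 to between 0.00785 and 0.0474. They could hardly lower the list, so they do not decide about array scaling. The list's call was lost with an estimated correlation. Culture density is not recorded in the labels used here and stays open, as does a biological response to IWP2.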

How the results depend on the processing

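The sex-chromosome alternative was added after the data had been seen, and the others before. Causes were not tested unless an alternative's own construction gives them. Against a gene at the array floor a log2 difference shrinks with any offset. Over 332 differences of named genes and 24 alternatives, 7582 of 7786 values kept their direction and their side of the threshold, 195 were no longer called, 126 of these under treat with its minimum of 1, 6 became called and 3 turned. Skil with IWP2 was -0.13 as the mean of its probe sets, and without probe sets ending in _x_at or _s_at Xist with IWP2 was -0.011 and Acta2 for ESC minus IWP2 was 0.078. None of these 3 was called.

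Fewer genes are tested above the median of all probe sets, where 337 genes fell at least 2-fold with IWP2, 4193 were higher (815 at least 2-fold) in ESCs than with vehicle and 4401 (865) in ESCs than in both EpiSC groups. With an offset of 32 the 2-fold counts were 84 higher and 265 lower with IWP2, 812 higher for ESC minus vehicle and 843 higher for ESC minus both. At an adjusted p under 0.01, 3886 genes were called with IWP2 (1847 higher, 2039 lower). Treat called 345 (51 and 294) with IWP2, 2148 (907 and 1241) for ESC minus vehicle, 2279 (1049 and 1230) for ESC minus IWP2 and 2236 (982 and 1254) for ESC minus both. On autosomes alone 11558, 10796 and 11976 genes were called in the 3 ESC comparisons.

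The correlation of both differences was -0.020 with all probe sets, -0.066 above the median, -0.043 with the offset, -0.024 after repeated quantile normalization and -0.024 after cyclic loess. The range with no effect held noise alone and was simulated for the main setting alone, so it decides nothing for these. Leaving out single arrays gave -0.022 to 0.0013.

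With the correlation estimated, the primitive streak list was not called with IWP2 (adjusted p = 0.152, range over its alternatives 2.38e-06 to 0.152). Fry, which does not set a list against other genes, called primed epiblast lower (1.34e-05) and turned naive pluripotency (0.0326) and neurectoderm (0.00364) with IWP2 and neural crest (0.0232) for ESC minus IWP2. Across all lists and comparisons, the estimated correlation ended 21 of 81 values' calls and fry added 38.

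Without single arrays, IWP2 calls ranged from 4949 to 5965, 155 to 188 rose and 509 to 525 fell at least 2-fold, and calls for ESC minus vehicle ranged from 11077 to 12115 and for ESC minus IWP2 from 10565 to 11323. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.060 to 0.051, and 0 arrays correlated best with their own number in both other groups. With the number as a block 5754, 12024 and 11138 genes were called in the 3 pairwise comparisons.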

Other observations

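Imprinted genes, which are expressed from 1 parental allele, were lower with IWP2 for 10 of 22 measured members and higher for 3 (camera adjusted p = 0.00296, and 0.0597 with an estimated correlation). Plagl1 differed by -2.14, Peg3 by -1.93, Phlda2 by 0.76 and Meg3 by 0.73. In ESCs against vehicle EpiSCs 11 were higher and 9 lower (adjusted p = 0.962), with Meg3 at 3.38 and Plagl1 at 2.69 higher and Grb10 at -3.16 lower. Of 12 LIF/STAT3 target genes, 5 were lower with IWP2 and 2 higher (adjusted p = 0.0461, and 0.446 with an estimated correlation), among them the LIF receptor gene Lifr (-1.76) and the kinase gene Pim3 (0.61). The enzymes of DNA methylation and demethylation gave no list call with IWP2 (2 higher and 1 lower of 8, adjusted p = 0.891) nor in ESCs against vehicle (5 higher and 2 lower, adjusted p = 0.193). In that comparison Dnmt3l was higher by 5.16 and Tet2 by 3.47, and Dnmt3b differed by -1.42.

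The next lists, up to the germline genes, are given for IWP2 minus vehicle. The p53 target list had 3 higher and 5 lower of 13 (adjusted p = 0.467), with Pmaip1 at 1.31 and Cdkn1a at -0.96. The unfolded protein and stress response list had 4 higher and 4 lower of 17 (adjusted p = 0.809). With 1 probe set per gene, none of 22 oxidative phosphorylation genes was called by limma (0 higher and 0 lower, adjusted p = 0.856, fry adjusted p = 0.845), and at an unadjusted p under 0.05 it was 1. Of the 4 probe sets of Ndufs4, 2 were called lower when tested separately. Of 15 glycolysis genes 4 were higher, Aldoc by 1.41, and 1 lower (adjusted p = 0.143). Of the Hox genes 2 of 22 were lower (adjusted p = 0.826), and of the germline genes 2 of 16 were higher (adjusted p = 0.26). Of the 2-cell-stage genes 4 were measured, too few for a test. With IWP2 1 of these was lower, and in ESCs all 4 were higher, Zfp352 by 2.15. In ESCs against vehicle, the lists of neurectoderm (adjusted p = 0.431), neural crest (0.891), trophoblast (0.998), Nodal/Activin targets (0.1), Hox genes (0.164), p53 targets (0.962), stress response (0.297), proliferation (0.87) and oxidative phosphorylation (0.594) were not called. Tfap2c of the trophoblast list was higher by 4.25, Gdf3 of the Nodal list by 5.35, and Ets1 of the neural crest list differed by -4.30.

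Chromosome 14 stood second to X in the ESC comparison. Its 374 genes above the median signal had a median ESC minus EpiSC difference of 0.22, with 55.6% called higher and 29.1% called lower, and the next highest autosome, chromosome 16, had a median of 0.0581. Between the 2 EpiSC groups, the medians of chromosomes 14 and X were 0.0104 and 0.0149. This was chosen after the values were seen, and its origin was not tested.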
